A study of Arabidopsis thaliana with 6 samples.

How the data were processed

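Total RNA from Arabidopsis thaliana plants was measured on 6 Affymetrix ATH1 arrays, on which each transcript is read by a probe set, a group of short probes summarised into 1 value. Per the labels, the plants were 4 weeks old and had received NaCl at 200 mM, lasting 3 h. Groups and replicate numbers came from the sample titles, which give 3 arrays of an ANAC069 overexpression line (OE) and 3 arrays of an ANAC069 knockout line (KO). The series design text calls the replicates of a group independent biological replicates.

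The deposited value table holds the authors' intensity of 22810 probe sets on each array on a linear scale. Per the submitters' processing notes these values came from MAS5, and no version is given in the sources used here. From the values, each array was scaled to a mean near 500 after the lowest and the highest 2% of its probe sets were left out. Array medians lay between 150 and 186, and between 16.1% and 19.7% of probe sets had a signal under 16. Detection calls were not used here. The number of arrays limits the precision of every value below.

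A pair of further tables deposited by the authors lists probe sets that they called up or down, with a p-value and an absolute fold for each. The direction was read from the values: the signed log2 of the deposited fold matched the log2 ratio of the geometric mean signals, OE over KO, to within 6.86e-06. The test behind the deposited p-value is not given in the sources used here, but the p matched that of an equal-variance comparison of group means on log2 signals to within 1.06e-06. Each listed probe set met an unadjusted limit of 0.05 and a fold of at least 2. Among all probe sets of the arrays, 954 met both limits, and the 387 that the authors did not list had a median mean signal of 16.1, against 394 for those listed. After Benjamini-Hochberg adjustment, 1 probe set passed 0.05 with that comparison. These tables also hold 48 columns of per-array values under names that match no sample label, and no such column was used in any step.

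Gene names came from the same pair of tables, since no annotation of the remaining probe sets was used here. Of their 567 probe sets, 541 carried 1 gene identifier found in NCBI RefSeq's gene table (assembly TAIR10.1, used for names only), 21 named several genes and were left unnamed, 4 named no gene and 1 carried an identifier not found there. The other 22205 probe sets outside the controls have no name here. A statement on a gene group therefore covers only its members in the authors' tables, and a gene absent from the text was not shown to be unchanged.

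The comparison of OE with KO used limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of variance on mean level) on log2(signal + 16), with group as the only term and no scaling beyond that of the authors. The 64 control probe sets were left out, as were probe sets whose mean log2 value was at or below the 30th percentile, which left 15922. Benjamini-Hochberg adjusted p-values were two-sided and the threshold was 0.05. Fold changes are on the log2(signal + 16) scale, which understates the change of dim probe sets. Means and SDs are of the linear signals. A gene with several probe sets was represented by the one with the highest mean.

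A set of 21 gene lists with 574 loci, the test, its covariates and the rule for named genes were fixed before the data were examined. The rule took ANAC069 and its chromosomal neighbours ANAC067 and ANAC068 (neither of which has a named probe set here), the 10 genes with the largest log2 fold change in each direction among calls whose groups did not overlap, and up to 4 members of each list. The planned list test (camera and fry of limma) needs named genes across the array and could not be run. In its place, a two-sided Fisher's exact test compared the numbers of called-higher and called-lower genes inside a list with those among the other named genes. The same test was run on 76 Gene Ontology terms with at least 10 named genes, on the authors' up and down tables. Both tests, and the naming of up to 4 genes for each of 7 such terms, were chosen after the data were seen. Annotation text in the tables ends at 255 characters per cell, so terms were taken from the identifier column. Genes of a term are co-regulated and terms share genes, so these p-values treat as independent what may not be.

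Ratios of 3' to 5' probe sets of the actin, GAPDH and ubiquitin controls served as signs of RNA quality and were compared between groups with exact permutation tests (SciPy 1.17.1). Spike-in controls were summarised as geometric means. The limma steps were tested on simulated arrays with 200 changed probe sets, of which 99 changed 2-fold and 92 changed 4-fold were among the 15922 tested. The share called was 56.6% at 2-fold and 96.7% at 4-fold, with 6 false calls. Noise was drawn independently for each probe set and array. The simulation therefore does not measure false calls from effects shared across an array, such as RNA quality. In 100 simulations of the direction test on 541 genes with 60 terms of 30 genes, the planted term was found in 100% and 2 other terms passed. The planted term had 29 of its 30 genes up, so this does not show how often smaller lists or weaker splits would be found.

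The alternatives were pseudocounts of 1 and 64, quantile normalization, a shift of each array to the same median, no filter or a filter at the 50th percentile, eBayes without a trend or with robust estimation, replicate number as a block, and each array left out in turn. A further pair of alternatives was added after the data were seen, namely the mean log2 3' to 5' ratio as a covariate and a fit without KO replicate 1 and OE replicate 2. To weigh OE replicate 2 by itself, probe sets were chosen by that array minus 1 KO array and measured on the 4 others, a test chosen after the results were seen. Its bound was also written after the results were seen, for both directions at once, and was met by the rise only. The fold that the calls kept without that array was not used for this, since calls are picked for groups that differ on all arrays, that one included.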

Results

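The series asked which genes ANAC069, a NAC-domain transcription factor of Arabidopsis thaliana, controls under salt. Plants of an overexpression line (OE-3) and of a SALK insertion line in which the gene is knocked out (KO-2) were compared after 200 mM NaCl for 3 h, with 3 ATH1 arrays per genotype. No untreated or wild-type plants were analysed here, so each value below is a difference between the genotypes under salt. Whether OE or KO departed from wild type was not measured. Log2(signal + 16) values correlated at 0.962 to 0.975 between arrays of the same genotype and at 0.945 to 0.968 between genotypes, over probe sets, which are not independent replicates.

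The ANAC069 transcript (AT4G01550, listed as NAC069, on chromosome 4 from 674024 to 676225 on the minus strand in the authors' deposited table, genome build not given in the sources used here) was far more abundant in OE. Its signal was 2579 ± 357 (SD, n = 3) in OE and 380 ± 14.4 (SD, n = 3) in KO. The log2 fold change was 2.70 (SE 0.14), a 6.51-fold difference with an adjusted p of 0.000362 in limma. Each OE array was above each KO array. The KO signal was well above the dim end of the arrays, and where the probes lie relative to the insertion is not given in the sources used here, so this value does not show how much intact transcript KO plants had.

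**Figure D1:**
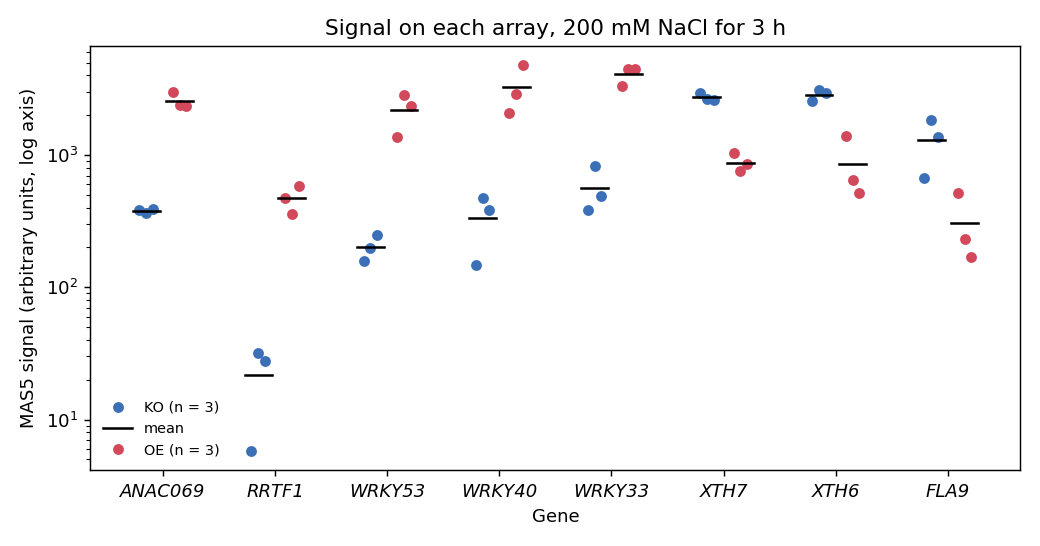
Signal of ANAC069 and of 7 of the most changed genes (x axis) on each of the 3 KO and 3 OE arrays (points), with the group mean as a black line, on a log axis in arbitrary MAS5 units. ANAC069 rose from a mean of 380 in KO to 2579 in OE, and the OE and KO points of each gene shown do not overlap.

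Under salt, OE plants had higher transcript levels of many named stress and defence regulators than KO plants. Named genes of cell wall loosening and of ribosomes had lower levels in OE. Few or none of these falls passed without KO replicate 2, OE replicate 2 or OE replicate 3, and the rises lost calls there too. RNA quality could not be told apart from the genotype as a cause of the falls (below). Of the 15922 probe sets tested, 483 were higher and 293 lower in OE at an adjusted p under 0.05. At least 2-fold changes made up 389 of these, 280 higher and 109 lower. The 3 OE and 3 KO values did not overlap in 4970 of the tested probe sets (31.2%), where chance gives 10%. The balance of directions moved with the scaling: 62.2% of calls were higher in OE as deposited, and 84.7% (794 higher, 143 lower) after each array was shifted to the same median, which moved the median log2 change of all tested probe sets from -0.08 to 0.09. Without KO replicates 1, 2 and 3 and OE replicates 1, 2 and 3 in turn, 548, 153, 243, 509, 66 and 88 probe sets were higher, 852, 7, 37, 587, 7 and 11 were lower, and 811, 156, 241, 639, 72 and 94 changed at least 2-fold.

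**Figure D2:**
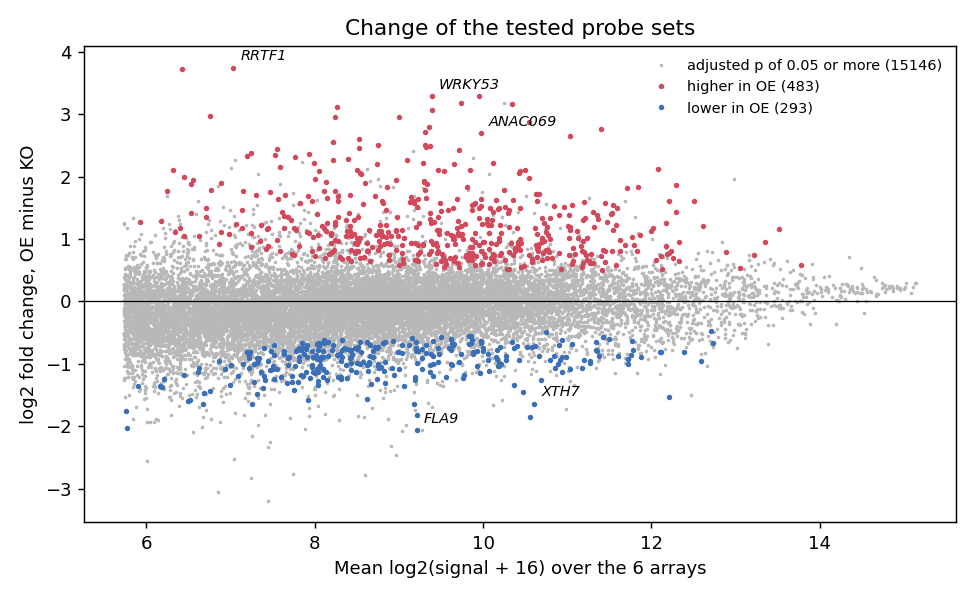
Log2 fold change of OE minus KO (y axis) against the mean log2(signal + 16) over the 6 arrays (x axis), a point for each tested probe set. Red points are the 483 probe sets higher in OE, blue points the 293 lower in OE, and grey points those that did not pass; the largest changes, such as RRTF1 at 3.75, lie on the higher side.

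Regulators of transcription led the named genes that rose in OE. RRTF1 (AT4G34410), an ERF transcription factor of redox responses, had a signal of 21.8 ± 14.0 (SD, n = 3) in KO and 472 ± 112 (SD, n = 3) in OE, a log2 fold change of 3.75 (SE 0.33, adjusted p = 0.00385). WRKY53 (AT4G23810), a WRKY factor of senescence and defence, went from 202 ± 46.1 to 2177 ± 749, a log2 fold change of 3.29 (SE 0.27). WRKY40 rose by 3.28 (SE 0.43), the salt-inducible zinc finger gene SZF1 by 3.16 (SE 0.44), the ERF gene ORA47 by 3.07 (SE 0.52) and WRKY33 by 2.88 (SE 0.26) on the log2 scale. LYK5 (AT2G33580), a receptor kinase of chitin perception, rose by 2.79 (SE 0.26). AT4G29780, AT5G52050 and AT2G22880, named here by locus, had log2 fold changes of 3.18, 2.95 and 2.97 with adjusted p-values of 0.0472, 0.00426 and 0.0373.

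The named genes that fell most included those of cell wall proteins. The fasciclin-like arabinogalactan protein gene FLA9 (AT1G03870) fell from 1296 ± 582 in KO to 306 ± 186 in OE (SD, n = 3 each), a log2 fold change of -2.06 (SE 0.44, adjusted p = 0.0408). The xyloglucan endotransglucosylase genes XTH6, XTH7 and XTH8 had log2 fold changes of -1.85 (SE 0.32), -1.64 (SE 0.15) and -1.56 (SE 0.33). SAUR15, a small auxin-induced gene, was at -1.57 (SE 0.25), and the cyclin gene CYCA3;2 at -1.58 (SE 0.37). Of the genes named by locus, AT1G04040 was at -1.82, AT2G44830 at -1.65, AT1G75580 at -1.64 and AT4G34760 at -1.64.

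Of the 54 named genes that passed in limma, 10 passed with each array left out in turn, namely ANAC069, RRTF1, WRKY53, AT5G52050, WRKY33, LYK5, XTH7, LOX3, CNI1 and SOBIR1. Among the other named genes, leaving out OE replicate 3, OE replicate 2, KO replicate 2, KO replicate 3, OE replicate 1 or KO replicate 1 ended 41, 40, 34, 27, 8 or 2 calls.

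The list of CBF, DREB and other early stress regulators held the most members that rose. All 10 of its 24 loci that had a named probe set rose in OE and none fell. Besides WRKY40 and WRKY33 these included ZAT10, a salt tolerance zinc finger gene (log2 fold change 2.66, SE 0.61), the calmodulin-like gene CML38 (2.61, SE 0.58), CBF1, DREB2A, AZF1, AZF2, ZAT6 and TCH3. The share of higher genes exceeded that of the other named genes in the authors' deposited tables (10 up, 0 down, Fisher's exact adjusted p = 0.0383). Among the limma calls the list also had the larger share of higher genes (10 higher, 0 lower, unadjusted Fisher's exact p = 0.0356). After adjustment over the 9 lists with a called member, it did not pass there (adjusted p = 0.160). Its members are in those tables because the authors selected them on these samples, so their common direction is not independent evidence. Without KO replicate 1 all 10 passed and so did the direction test on the limma calls (adjusted p = 0.0361). Without KO replicates 2 and 3 and OE replicates 1, 2 and 3 in turn, 8, 7, 8, 3 and 5 members passed, and 9 did with the 3' to 5' ratio of the control genes, which was higher in OE, as a covariate (below).

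**Figure D3:**
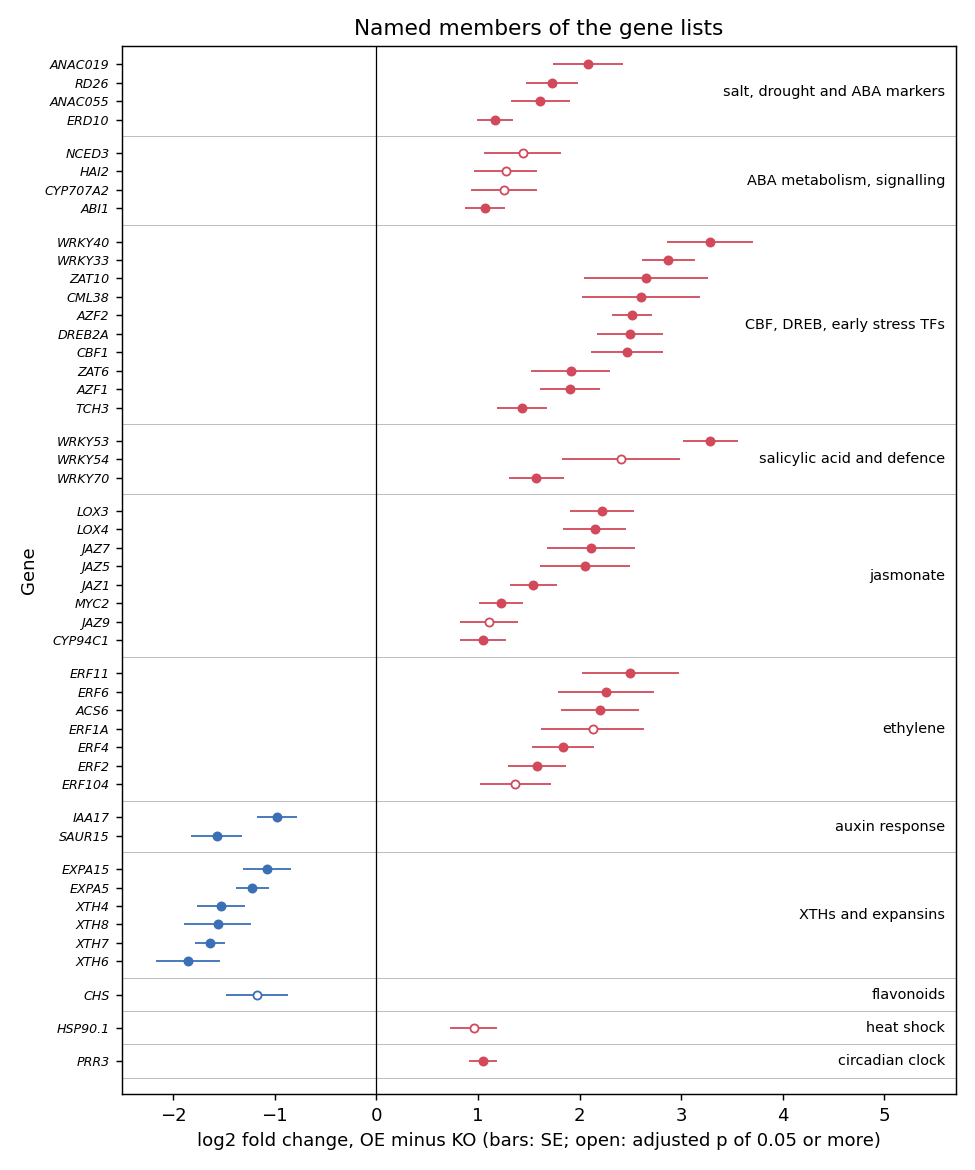
Log2 fold change of OE minus KO (x axis) of the 47 list members with a named probe set (y axis, grouped by list), with bars for the SE of the limma fit, red for above 0 and blue for below. Open symbols mark the members with an adjusted p of 0.05 or more. All named members of the jasmonate (8), ethylene (7) and early stress (10) lists lie above 0, and all 6 xyloglucan endotransglucosylases and expansins lie below 0.

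Genes of jasmonate and ethylene responses lay on the higher side too. Of the 32 jasmonate loci, 8 had a named probe set and 7 rose, including the lipoxygenase genes LOX3 (log2 fold change 2.22, SE 0.31) and LOX4 (2.15, SE 0.31), the repressor genes JAZ7 (2.11, SE 0.44) and JAZ5 (2.06, SE 0.44), JAZ1 and the transcription factor gene MYC2. Of the 23 ethylene loci, 7 had a named probe set and 5 rose, among them ERF11 (2.50, SE 0.48), ERF6 (2.26, SE 0.47), ERF4 (1.84, SE 0.31) and ACS6 (4.61-fold higher, SE 0.38 on the log2 scale), which encodes an enzyme of ethylene synthesis. Neither list passed the direction test against the other named limma calls (Fisher's exact adjusted p = 0.238 and 0.493). All called members rose, the most extreme outcome, yet the unadjusted p was 0.106 and 0.329. The test could therefore not pass with so few called members, and it does not show that direction was the same. Without OE replicate 2 and OE replicate 3, 2 and 1 jasmonate members passed, against 1 and 0 of ethylene. Without KO replicates 1, 2 and 3 and OE replicate 1 the numbers were 6, 1, 5 and 4 for jasmonate and 6, 4, 0 and 5 for ethylene. The ratio covariate left 4 and 3.

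The named salt, drought and abscisic acid (ABA) markers rose. Of 30 salt, drought and ABA marker loci, 4 had a named probe set and all 4 rose: the NAC genes ANAC019 (log2 fold change 2.09, SE 0.34), RD26 (1.73, SE 0.25) and ANAC055 (1.61, SE 0.29) and the dehydrin gene ERD10 (1.17, SE 0.18), whose signal went from 7834 ± 884 to 17801 ± 3614 (SD, n = 3 each). None of the 4 passed without KO replicate 2, OE replicate 2 or OE replicate 3, and 1 did with the ratio covariate. Of 36 loci of ABA metabolism and core signalling, 4 had a named probe set and 1 passed, the phosphatase gene ABI1 (1.07, SE 0.20). It did not pass without KO replicate 2, KO replicate 3, OE replicate 2 or OE replicate 3, while 3 of the 4 passed without OE replicate 1 or with quantile normalization and all 4 after the shift to the same median, against 0 with the ratio covariate. The direction test against the other named limma calls did not pass for either list (Fisher's exact adjusted p = 0.493 and 1.0). With so few called members, all higher, it could not have passed (unadjusted p = 0.318 for the markers). In the salicylic acid and defence list (24 loci, 3 named) WRKY53 and WRKY70 (1.57, SE 0.27) rose. The direction test (adjusted p = 1.0) could not pass with 2 called members. WRKY70 did not pass without KO replicate 2, OE replicate 2 or OE replicate 3. All 3 named members passed without KO replicate 3 or OE replicate 1, and with the ratio covariate.

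Xyloglucan endotransglucosylases and expansins, which loosen and remodel the wall of growing cells, fell in OE. Of 25 loci, 6 had a named probe set and all 6 fell, XTH4 from 8129 ± 1762 to 2831 ± 784 (SD, n = 3 each, log2 fold change -1.53, SE 0.23), XTH6, XTH7 and XTH8 as above, EXPA5 and EXPA15. Of the 9 lists with a called member, only this one passed the direction test against the other named limma calls (Fisher's exact adjusted p = 0.00671). Within each of the 9, all called members went in the same direction. Lower was the rarer direction among the named calls (268 higher, 118 lower), so a wholly lower list passes more easily than a wholly higher one. In the authors' deposited tables this list stood at 0 up and 6 down (adjusted p = 0.0383). The list test did not pass without KO replicate 2 (adjusted p = 0.321), OE replicate 2 (0.226) or OE replicate 3 (0.190), when 1 member was called, nor with the ratio covariate (1 member, 0.213) or without KO replicate 1 and OE replicate 2 (4 members, 0.106). Both named members of the auxin response list (28 loci), SAUR15 and IAA17 (-0.98, SE 0.20), fell, with a Fisher's exact adjusted p of 0.238 for direction. That test could not pass with 2 called members, both lower (unadjusted p = 0.0929). Without KO replicate 3, OE replicate 1, OE replicate 2 or OE replicate 3 only 1 of the pair passed, and without KO replicate 2 neither did. With the ratio covariate 1 passed.

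Across the 21 lists, 47 loci had a named probe set, of which 38 passed over all probe sets tested and 47 when adjusted over the list alone; the latter is not independent evidence, since the authors chose these genes on the same samples. The clock gene PRR3 rose (1.05, SE 0.14), the only named member of its 21 loci, and did not pass without OE replicate 3 or with the ratio covariate. The chalcone synthase gene CHS of the flavonoid list (15 loci) had a log2 change of -1.17 (SE 0.30, adjusted p = 0.0625) and the heat shock gene HSP90.1 (24 loci in its list) one of 0.96 (SE 0.23, adjusted p = 0.054), and neither passed. CHS passed without KO replicate 1 (adjusted p = 0.0468) and with the filter at the 50th percentile (0.0499), and HSP90.1 passed with either rescaling of the arrays (0.0311 and 0.0234). The other 10 lists (292 loci) had no member among the named probe sets: superoxide dismutases, catalases and ascorbate-glutathione enzymes, glutathione S-transferases, class III peroxidases, proline metabolism, sodium, potassium and proton transport, aquaporins, photosynthesis, and markers of roots, flowers and seeds. Their levels were not analysed here.

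Gene Ontology terms, tested on the authors' deposited up and down tables, split by direction in 32 of 76 cases. Of 44 genes annotated to the response to chitin, a component of fungal walls, 43 were in the up table and 1 in the down table (Fisher's exact adjusted p = 1.48e-07), and limma called 40 higher and 1 lower. Defence response had 35 up and 1 down (adjusted p = 2.00e-06) and transcription factor activity 56 up and 8 down (adjusted p = 3.34e-06). Chitin-response genes called higher numbered 12 without OE replicate 2, 13 without OE replicate 3, 23 without KO replicate 3 and 27 without KO replicate 2. With the same arrays left out, in that order, 7, 5, 19 and 12 defence genes (31 with all arrays) and 16, 19, 33 and 36 transcription factor genes (47 with all arrays) were called higher. With the ratio covariate 26 chitin, 11 defence and 32 transcription factor genes were. These genes include RRTF1, WRKY53, WRKY40 and SZF1 above, and CNI1 (AT5G27420), a RING ubiquitin ligase gene of the defence term, was 4.59-fold higher (SE 0.25 on the log2 scale).

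Ribosomal genes lay on the lower side. All 17 named genes annotated as structural constituents of the ribosome were in the down table (Fisher's exact adjusted p = 2.00e-06), and limma called 10 of them lower and 0 higher. Among those called, the largest falls were those of AT1G07070, AT4G10450, AT5G47700 and AT5G64650, with log2 fold changes of -1.22 (SE 0.25), -1.19 (SE 0.22), -1.13 (SE 0.24) and -1.13 (SE 0.22). Ribosome biogenesis stood at 0 up and 10 down (adjusted p = 0.000566), with 7 genes called lower, AT3G03920 (-1.18, SE 0.22), AT4G12600 (-1.14, SE 0.19) and AT3G06680 (-1.12, SE 0.22) among them. Without KO replicate 2, KO replicate 3, OE replicate 2 or OE replicate 3 none of the ribosomal calls of either term passed in limma, against 15 and 14 structural constituents without KO replicate 1 and OE replicate 1. With the 3' to 5' ratio of the control genes, higher in OE on average, as a covariate, 0 genes of either term were called lower. This covariate raised the median SE of the 293 called-lower probe sets from 0.18 to 0.27. Whether the ratio moved with the ribosomal genes within groups was not tested. RNA quality cannot be told apart from the genotype as a cause of their fall (below). Cell wall genes stood at 1 up and 14 down (adjusted p = 0.000162), with 10 called lower, and 1, 4, 1 and 1 called lower without KO replicate 2, KO replicate 3, OE replicate 2 and OE replicate 3, and 1 with the ratio covariate.

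The authors' deposited tables list 341 probe sets up and 226 down in OE, and in their deposited table ANAC069 is 6.74-fold up. Of their 567 probe sets 566 were tested in limma, and 410 passed, all 410 in the authors' direction. Of the 389 limma calls of at least 2-fold, 381 are in those tables, while 366 of the 776 calls of any size are not. The authors' folds and the limma fit come from the same arrays, so neither the shared direction nor this overlap is independent evidence.

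Signs of RNA quality separated the genotypes in 3 of 6 control ratios, with the higher values in OE. The 3' to 5' signal ratio of 1 actin control was 5.41 ± 0.35 (SD, n = 3) in OE and 3.96 ± 0.54 (SD, n = 3) in KO, and that of a GAPDH control was 3.09 ± 0.06 in OE and 2.42 ± 0.33 in KO. The second GAPDH control gave 1.35 ± 0.10 against 1.15 ± 0.06, and for these 3 controls each OE array was above each KO array (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 can give; adjusted p = 0.2 over 6 ratios). The other actin ratio and both ubiquitin ratios overlapped between groups (exact permutation p = 0.4, 0.6 and 0.5). In these, KO replicate 1 was above OE replicate 3, at 20.5 against 16.5, 3.56 against 2.90 and 1.66 against 1.39. It was above OE replicate 3 in the mean log2 ratio as well, so that mean does not separate the groups on every array. With the mean log2 ratio as a covariate, an alternative chosen after the data were seen, 189 probe sets were higher and 19 lower. The members of each gene group called with it are given above.

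**Figure D4:**
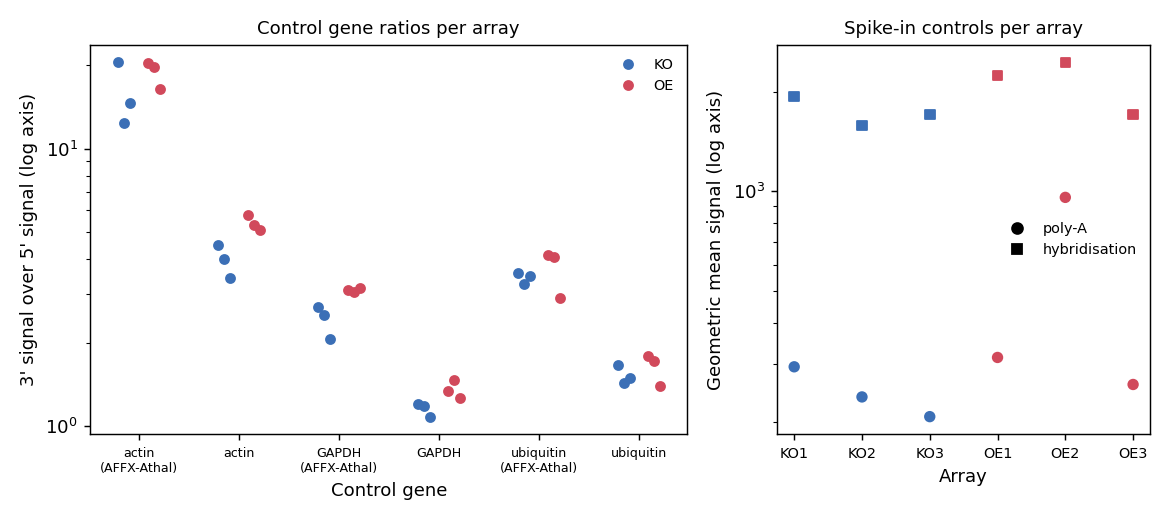
Left, 3' over 5' signal ratio (log axis) of 6 control pairs on each KO and OE array, with OE above KO on each array for 1 actin and both GAPDH pairs. Right, geometric mean signal (log axis) of the poly-A and hybridisation spike-in controls on each array, where OE replicate 2 reaches 958 for the poly-A controls and the other arrays lie between 208 and 314.

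Poly-A spike-in controls, bacterial RNAs added before labelling, had a geometric mean signal of 958 on OE replicate 2 and of 208 to 314 on the other 5 arrays. Without OE replicate 2 alone, 66 probe sets were higher and 7 lower in OE. With it left out, 3 early stress regulators were called higher and 1 xyloglucan endotransglucosylase or expansin lower. Without KO replicate 1 and OE replicate 2, a pair chosen after the data were seen, 154 probe sets were higher and 190 lower in OE. That fit called 7 early stress regulators higher and 4 xyloglucan endotransglucosylases and expansins lower. Leaving out KO replicate 1 alone gave 548 higher and 852 lower, so the pair does not measure the weight of OE replicate 2.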

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

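The comparison of 3' to 5' ratios between groups was planned before the data were examined; the tests of chance, RNA quality, array brightness and the weight of OE replicate 2 were chosen after the results were seen.

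The control genes, which the comparison of genes does not use, had higher 3' to 5' ratios on the OE arrays: 5.41 for actin, 3.09 and 1.35 for the GAPDH pairs, each above every KO array. If lower RNA quality in OE were the cause of the changes, the ratio would track these probe sets within groups too; for the 483 higher in OE the change it predicts was a median of -10.3% of that observed (quartiles -27.0% and 7.44%, and medians of -12.8% to -6.25% with each array left out). Calls favour probe sets with little scatter within groups, so the test was repeated on the 483 probe sets with the largest rise by fold alone. The median there was -26.6% (quartiles -51.8% and -5.33%). Both argue against RNA quality, as the mean log2 ratio measures it, as the whole cause of the rise. The quartiles are over probe sets and do not give the uncertainty from the few arrays. Some ratios in that mean did not separate the groups, and those that did were not tested by themselves. For the 293 lower in OE the median was 13.3% (-5.06% to 25.1% with each array left out), but for the 293 largest falls by fold alone it was 38.3% and ran from -20.4% to 75.7%, so RNA quality cannot be told apart from the genotype as a cause of the falls, ribosomal and wall genes included, with 6 arrays. With the ratio as a covariate 145 of the 483 and 10 of the 293 still passed, while their median log2 changes went from 1.09 to 1.17 and from -0.91 to -0.77 and the median SE from 0.19 to 0.27 and from 0.18 to 0.27; the genotype stays open for both sets.

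The poly-A spike-in controls reached a geometric mean of 958 on OE replicate 2, 3.64 times the mean of the other arrays, and each of the 24 probe sets was highest there. The hybridisation controls were also highest on that array, at 2454, which is 1.34 times the mean of the others, so a brighter array alone is unlikely to account for the poly-A value; more spike-in per RNA added could give it, and remains open since no value here measures it. In the 483 probe sets highest in OE replicate 2 over 1 KO array, the 4 arrays not used in that choice had a median log2 change of 0.76 to 1.03 over the 3 KO arrays, against at most 0.24 when those 4 were split in other ways, which argues against that array alone carrying the rise in OE. For the 293 lowest chosen with KO replicate 1 the median was -0.74, against at most 0.14 in size in other splits. Chosen with KO replicates 2 and 3 it was -0.71 and -0.55, but other splits reached 0.92 and 0.82 in size. Whether OE replicate 2 carries the fall therefore stays open. Without that array limma called 73 probe sets (68 of them among the 776), against at most 4 in the 9 other splits of the 5 arrays left. Those splits are too few for a share under 0.05, and the part of OE replicate 2 in the size of the changes stays open.

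For the counts of calls, 1 of the 10 splits of the 6 arrays into 3 and 3, the real one, gave as many probe sets higher (483, highest other split 4), lower (293, highest other 4), changed at least 2-fold (389, highest other 4) and lists past the threshold (1, highest other 0). A set of 10 splits is too few for a share under 0.05.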

How the results depend on the processing

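The ratio covariate, the fit without KO replicate 1 and OE replicate 2, and the direction test in place of camera were chosen after the data were seen. ANAC069 passed under every alternative, with a log2 fold change of 2.56 to 2.87 and an adjusted p of 0.00014 to 0.00963. The OE and KO values of all 776 called probe sets did not overlap, so most alternatives, arrays left out included, could not turn their direction; quantile normalization, the median shift and the ratio covariate could, and all 776 kept it there. Of the 54 named genes that passed, 8 did so under each alternative. Counts moved by more than 1.5 times in these settings. Shifting arrays to the same median gave 794 higher and 143 lower, and took ABA metabolism and signalling from 1 called to 4 and auxin response from 2 to 1. No filter gave 261 higher, 76 lower and 219 of at least 2-fold, with 22746 probe sets sharing the adjustment. It took jasmonate from 7 to 4, ethylene from 5 to 3 and auxin response from 2 to 1. eBayes without a trend gave 161, 43 and 170, and the cause was not tested. Called members fell from 5 to 0 for ethylene, 6 to 3 for xyloglucan endotransglucosylases and expansins, 10 to 6 for early stress and 7 to 4 for jasmonate. They fell from 4 to 2 for salt markers, 1 to 0 for ABA metabolism and signalling, and 2 to 1 for auxin response and for salicylic acid and defence. The ratio covariate gave 189, 19 and 208 with 0 lists, at a larger SE. Without KO replicate 1 and OE replicate 2 there were 154 higher, 190 lower and 0 lists, from 4 arrays. With 1 array left out, from 5 arrays, the counts ranged from 66 to 548 higher, 7 to 852 lower, 72 to 811 of at least 2-fold and 0 to 2 lists. Replicate numbers did not pair the arrays, since same-numbered deviations correlated at -0.24, -0.12 and 0.06 and only OE replicate 3 correlated best with its own number. With replicate number as a block 238 were higher, 37 lower and 253 at least 2-fold, with 2 fewer residual degrees of freedom. Salt markers went from 4 to 2 there, ABA metabolism and signalling from 1 to 0 and auxin response from 2 to 1. The other settings kept these totals within 1.5 times, but not each list: ABA metabolism and signalling went from 1 called to 3 with quantile normalization and 2 with robust eBayes, ethylene from 5 to 3 with robust eBayes, and CHS and HSP90.1 passed in 1 such setting each. Signals under 16, between 16.1% and 19.7% of probe sets per array, limit what can be said of dim transcripts.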

Other observations

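The annotation tests and the genes named for them were chosen after the data were seen. Receptor and other protein kinases lay mostly on the higher side in OE. Of 44 named genes with protein kinase activity, 37 were in the authors' deposited up table and 7 in the down table (Fisher's exact adjusted p = 0.00162), and limma called 31 higher and 2 lower. SOBIR1 (AT2G31880), a receptor kinase of immunity, went from 2629 ± 450 in KO to 9657 ± 2046 in OE (SD, n = 3 each, log2 fold change 1.86, SE 0.19, adjusted p = 0.00511). The cysteine-rich receptor kinase genes CRK23 and CRK7 had log2 fold changes of 1.99 (SE 0.39) and 1.96 (SE 0.40). Without KO replicate 2, KO replicate 3, OE replicate 2 and OE replicate 3, 9, 25, 6 and 6 kinase genes were called higher, and 16 with the 3' to 5' ratio as a covariate.

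Ubiquitin ligase genes were all on the higher side, with 10 up and 0 down (Fisher's exact adjusted p = 0.0196), and limma called all 10 higher. The U-box genes PUB19, CMPG1 and PUB22 had log2 fold changes of 2.36 (SE 0.40), 1.76 (SE 0.34) and 1.29 (SE 0.28). Response to wounding had 16 up and 1 down (adjusted p = 0.00653), response to oxidative stress 13 up and 1 down (adjusted p = 0.0281), response to abscisic acid 14 up and 1 down (adjusted p = 0.018) and response to cold 14 up and 2 down (adjusted p = 0.0485). The nucleolus had 1 up and 13 down (adjusted p = 0.000329). Response to auxin, with 4 up and 10 down, did not pass (adjusted p = 0.057). Nor did response to salt stress, with 11 up and 3 down (Fisher's exact adjusted p = 0.241). Response to water deprivation (12 up, 4 down, adjusted p = 0.370) and to jasmonic acid (10 up, 2 down, adjusted p = 0.198) did not pass either. Without OE replicate 2, 2 ubiquitin ligase, 4 wounding, 1 oxidative stress, 3 abscisic acid and 3 cold genes were called higher, and 0 nucleolus genes were called lower. Without OE replicate 3 the numbers were 3, 4, 3, 3, 4 and 0, without KO replicate 2 they were 4, 8, 6, 6, 6 and 0, and without KO replicate 3 they were 3, 7, 8, 8, 10 and 0. With the 3' to 5' ratio as a covariate they were 4, 10, 6, 7, 6 and 0, against 10, 16, 12, 12, 13 and 8 in the limma fit without it.

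Some large changes belong to probe sets with no gene name here. Probe set 255970_s_at had a signal of 9.19 ± 12.0 in KO and 297 ± 12.5 in OE (SD, n = 3 each), a log2 fold change of 3.73 (SE 0.33, adjusted p = 0.00385), and 252346_at went from 93.3 ± 37.8 to 959 ± 480, a log2 fold change of 3.11. On the lower side, 265955_at was at -2.03 (SE 0.33, adjusted p = 0.0206) and 246485_at at -1.76 (SE 0.40). They were picked by size after their values were seen.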
